A study of Mus musculus with 6 samples.

How the data were processed

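Total RNA from whole mammary glands of 6 female mice of a mixed 129, FVB and Black Swiss background was labelled with biotin and hybridised, 1 mouse per array, to a mouse 3' expression array, per the labels. The deposited values are MAS5 signal intensities, 1 per probe set, on a linear scale. MAS5 is the only tool that the submitters' processing notes name, and its version is not given in the sources used here. In the deposited values every array had a 2%-trimmed mean of 500, so the arrays had already been scaled to a common level. No detection calls or scanner images were used here, so signals were judged against probe sets that should be dark. In these female mice 20 probe sets of Y-linked genes had a median signal of 33.6 and a highest signal of 483.5, and 16 of their 120 values lay above the filter described next.

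The values were kept at their deposited scaling and turned into log2(signal + 52.1), where 52.1 is the 25th percentile of all values. A log2 ratio is therefore on the log2(signal + pseudocount) scale and understates the change of dim genes. Of 45101 probe sets, 64 were array controls, 34945 carried 1 gene symbol, 932 carried several and 9160 are unnamed here. Only probe sets with 1 symbol were used. They cover 18194 genes, of which 18032 were matched by gene ID to a RefSeq table of the GRCm38.p6 assembly, used for chromosomes and for the order of neighbouring genes; 0 symbols changed. Each gene was represented by its probe set with the highest mean, and probe sets prone to cross-hybridisation were taken only where a gene had no other. Genes with a mean log2 value under the median of all probe sets, 7.715, were not tested, which left 11495 genes. Trp53 is not analysed here.

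The 6 arrays form 3 pairs of a Brca1 mutant and a control at the same stage. The pregnant pair was taken at day 16.5 of pregnancy, at an age of 5 months. The virgin pair was 6 months old, and the lactating pair was taken on day 1 of lactation at 2 months. Pairing rests on the stage in the labels. Deviations from the genotype means correlated across genes within each pair, with r = 0.584 for the pregnant, 0.857 for the virgin and 0.819 for the lactating arrays (genes are not independent replicates). Mutant was compared with control in a limma linear model (limma 3.58.1, R 4.3.3; eBayes with a variance trend) with the stage as a block, which leaves 2 residual degrees of freedom and a prior of 5.578. The pairs of stages were compared in the same model with genotype as a term, on 2 arrays per stage. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. Because each stage holds 1 pair, ratios within a stage carry no test. For those, a gene list's median was placed among 10000 random lists of the same size matched on mean signal in 10 bins, as a description of the 2 arrays.

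Gene lists for cell types, pathways and X inactivation, 29 of which had at least 5 tested genes, were tested with camera, two-sided, at a preset correlation of 0.01, and again with an estimated correlation and with fry. The X chromosome was tested the same way with its 342 tested genes. The comparisons, the gene lists, the rule for naming genes and all alternatives but 1 were chosen before the data were examined. The rule named Brca1 and Xist in every case. For mutant against control, where fewer than 10 genes passed, it named the 10 highest and 10 lowest moderated statistics among genes that moved the same way in all 3 pairs, and the 5 highest and 5 lowest on the X. Within a pair it named the 8 highest and 8 lowest ratios, and between stages the 10 largest and 10 lowest log2 ratios among called genes. For each list it named up to 4 members with the smallest p. Some of these are left out for brevity.

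The alternatives were quantile normalization, centring on array medians, a pseudocount of 14.9 or 168.7, no filter or a filter at the 75th percentile, the mean of a gene's probe sets, no variance trend, no block or no genotype term, and leaving out each pair or array. The alternative without the lactating arrays was added after seeing the data. The code was tested on simulated data with 200 changed genes among 11495. For mutant against control it recovered 20% of genes changed by a log2 ratio of 1, 88% at 2, 96% at 3 and 100% at 4, with 7 false calls. For lactating against virgin it recovered 22%, 86%, 100% and 100%, with 6 false calls. A simulated shift of 0.5 in a whole list gave a camera adjusted p of 9.721e-08 with the preset and 0.6311 with an estimated correlation. The simulated genes varied independently of each other, a setting that favours the low preset. Camera with an estimated correlation thus missed a true shift of that size among independent genes. The simulation cannot tell which setting is right for the real, correlated genes. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9.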

Results

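Gene expression was measured in mammary glands of 3 Brca1 mutant and 3 control mice, as 1 pair at each of 3 stages of the mammary cycle, to look for genes regulated by Brca1, a DNA repair and tumour suppressor gene, and among them genes on the X chromosome. The virgin and lactating mutants were homozygous for the germline allele D11, and these mice and their controls carried 1 normal copy of p53. The sample labels give the pregnant pair another genotype. Its mutant was homozygous for a conditional Brca1 allele, written co, with a Cre recombinase gene under the mouse mammary tumour virus promoter, and its control carried 1 conditional copy with the same Cre gene. The series' design text describes all mutants by the germline genotype, and the sample labels were followed here. The lactating arrays bear another array date than the other 4. Median signals were 120 to 158 in the pregnant and virgin arrays and 211 and 231 in the lactating mutant and control. The ratio of 3' to 5' beta-actin signal, which rises as RNA degrades, was 1.37 and 1.43 in the pregnant control and mutant, 2.74 and 2.04 in the virgin control and mutant, and 1.91 and 1.58 in the lactating control and mutant. The same ratio for Gapdh was 3.50 in the virgin control and 1.52 in the virgin mutant, and 0.73 to 1.20 in the other 4 arrays.

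Brca1 itself was dim. Its brightest probe set had signals of 159 in the control and 288 in the mutant of the pregnant pair, 137 and 487 in the virgin pair, and 238 and 157 in the lactating pair. The log2 ratio of mutant to control was 0.58 ± 0.37 (SE, n = 3 pairs; limma adjusted p = 0.938). All 4 Brca1 probe sets had positive log2 ratios in the fit. Their position relative to the deleted part of the gene is not given in the sources used here, so they do not check the mutation. Xist, the RNA that coats the inactive X chromosome, was bright on its brightest probe set, at 9393 to 13887 in all 6 arrays, and its log2 ratio was 0.01 ± 0.17 (SE, n = 3 pairs; limma adjusted p = 0.9915). The other 2 Xist probe sets had log2 ratios of -0.15 ± 0.16 and -0.43 ± 0.25 (SE). One of them read 783 and 848 in the virgin arrays, 4244 and 4956 in the pregnant arrays and 12475 and 15818 in the lactating arrays, while the brightest differed between stages by a log2 ratio of at most 0.29 in size.

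The X chromosome, the subject of the series, was not called as a group. The median log2 ratio of mutant to control was 0.01 over 342 X-linked genes and 0.03 over 11114 autosomal genes, a shift of -0.03 (camera p = 0.427, 0.568 with an estimated correlation; for X-linked genes against no change, not against autosomes, fry p = 0.756, mixed p = 0.568). By pair the shift was 0.01 in the pregnant, -0.08 in the virgin and -0.03 in the lactating glands (SD 0.047). The X median of the virgin pair stood at percentile 0.05 among random lists of matched signal, and those of the pregnant and lactating pairs at 79.5 and 21.2. No X-linked gene passed with limma, over all genes or adjusted over the list alone (0 of 342, lowest adjusted p = 0.990), and 9 had an unadjusted p under 0.05. In the mutant 36 X-linked genes were higher and 42 lower in all 3 pairs, 22.8% of those tested against 25.9% of autosomal genes and 25% by chance. Among 20 chromosomes the X ranked 19 by its median.

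**Figure D1:**
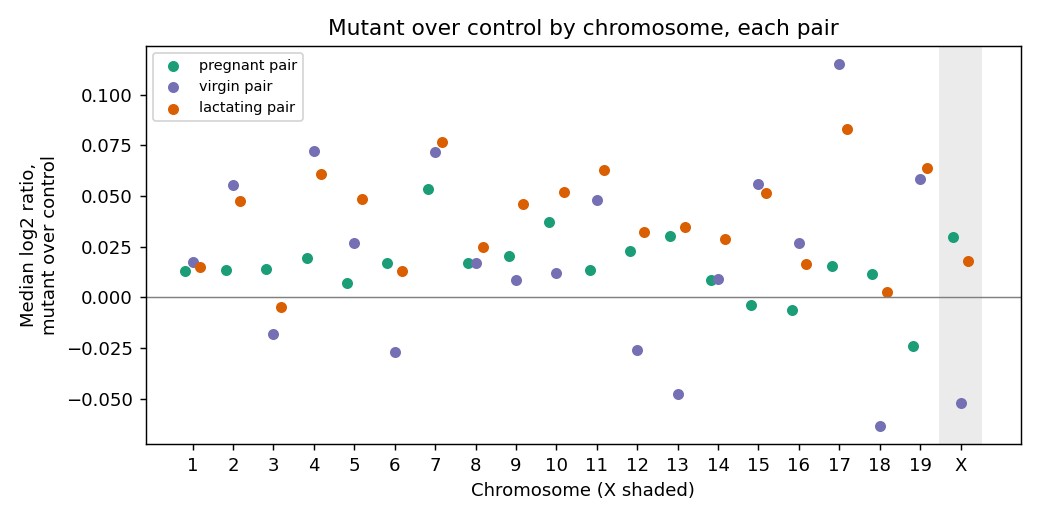
Median log2 ratio of mutant to control (vertical axis) for the tested genes of each chromosome (horizontal axis), 1 point per pair of arrays. The X lies at 0.03 in the pregnant, -0.05 in the virgin and 0.02 in the lactating pair, inside the range of the autosomes, and chromosome 17 is highest in the virgin and lactating pairs at 0.12 and 0.08.

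The X-linked genes with the strongest same-sign ratios were all below the threshold (limma adjusted p = 0.938 for each). Higher in all 3 mutants were Pola1, the catalytic subunit of DNA polymerase alpha, at a log2 ratio of 0.79 ± 0.23 (SE), the mitotic kinesin Kif4 at 0.58 ± 0.23, the deubiquitinase Otud5 at 0.41 ± 0.17, Capn6 at 0.54 ± 0.22 and the basement membrane collagen Col4a6 at 0.47 ± 0.20. The Otud5 value rests on 1 probe set, and 2 of its 4 probe sets had the opposite sign. The same holds for 1 of the 2 Syap1 probe sets. Lower in all 3 were Mpp1 at -0.50 ± 0.15, Prr32 at -0.94 ± 0.30, the copper-dependent iron oxidase Heph at -0.44 ± 0.17, Syap1 at -0.36 ± 0.15 and the pyruvate dehydrogenase subunit Pdha1 at -0.42 ± 0.19. The list of genes that escape X inactivation had a median of 0.01 over 17 genes (camera adjusted p = 0.929). The X inactivation machinery had a median of 0.11, with 21 of 24 genes higher in the mutant (camera adjusted p = 0.0539).

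Across the genome, 0 of 11495 genes passed the threshold between mutant and control (limma, lowest adjusted p = 0.938). An unadjusted p under 0.05 was reached by 540 genes, 319 higher and 221 lower, where chance alone gives 575. Ratios of mutant to control were nearly uncorrelated across genes between pairs, with r = 0.01 for pregnant and virgin, -0.04 for pregnant and lactating and 0.03 for virgin and lactating. The genes with the strongest same-sign ratios are given as values below the threshold (limma adjusted p = 0.938 for each). On the higher side were Gjb6, a gap junction protein, at a log2 ratio of 0.93 ± 0.15 (SE, n = 3 pairs), the heat shock protein Hsph1 at 0.98 ± 0.16, the ribonucleotide reductase subunit Rrm2 at 0.96 ± 0.17, Tcf19 at 0.92 ± 0.17, the DNA polymerase delta subunit Pold2 at 0.87 ± 0.17, the valyl-tRNA synthetase Vars at 1.26 ± 0.25, Uhrf1, which maintains DNA methylation, at 0.95 ± 0.21, and cyclin D1 (Ccnd1) at 0.90 ± 0.21. On the lower side were the phosphatase Dusp16 at -1.01 ± 0.17, nicotinamide N-methyltransferase Nnmt at -0.85 ± 0.16, the clock output genes Dbp at -1.03 ± 0.21 and Nr1d2 at -0.93 ± 0.20, the sarcomere gene Tcap at -0.95 ± 0.21, the acute phase gene Serpina3n at -1.14 ± 0.25 and the nuclear receptor corepressor Nrip1 at -0.63 ± 0.16. Without the lactating pair, the 4 arrays of 1 array date gave 2 calls, both lower in the mutant and both adipocyte genes: Lep, which encodes leptin, at -1.71 ± 0.18 and Sncg at -2.01 ± 0.22 (SE; limma adjusted p = 0.0353 each). In the lactating pair their ratios were 0.82 and -0.02. Lep falls outside the naming rule and was chosen after its values were seen.

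Genes of DNA replication were higher in the mutant as a group. All 28 tested S phase genes had a positive log2 ratio, with a median of 0.44 (camera adjusted p = 8.252e-14). The adjusted p was 0.792 with an estimated correlation, and fry gave p = 0.122. Medians were 0.72, 0.67 and 0.17 in the pregnant, virgin and lactating pairs, where 27, 28 and 18 of the 28 genes were higher. Over all genes 0 members passed, and adjusted over the list alone 2 did, Rrm2 and Uhrf1. Other members were Rrm1 at 0.88 ± 0.26 and Pola1 at 0.79 ± 0.23 (SE). In the same pairs, B and plasma cell genes had medians of 0.67, 0.44 and -0.29, and T cell genes of 0.40, 0.30 and -0.21.

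In all, camera called 9 of 29 lists, 4 higher and 5 lower in the mutant; 0 were called with an estimated correlation (lowest adjusted p = 0.792) and 0 with fry. Of the 9, S phase, endoplasmic reticulum stress and adipocyte genes had the same sign of median in all 3 pairs. The endoplasmic reticulum stress list had a median of 0.16, with 21 of 28 genes higher (camera adjusted p = 0.0313), among them the chaperone cofactor Sdf2l1 at 0.61 ± 0.16 and Creld2 at 0.75 ± 0.22 (SE), while Trib3 was at -0.79 ± 0.23. The adipocyte list had a median of -0.17, with 18 of 24 genes lower (camera adjusted p = 0.00054), among them the lipid droplet gene Plin4 at -0.52 ± 0.15 and Sncg at -1.35 ± 0.39 (SE). The other 6 changed sign between pairs. Mitosis genes had a median of 0.21 (camera adjusted p = 0.0422), with 1.10 in the virgin pair, where all 29 were higher, against -0.02 in the pregnant and -0.26 in the lactating pair. Skeletal muscle genes had a median of -0.36 (camera adjusted p = 8.491e-06), with -1.23 in the virgin pair, -0.12 in the lactating and 0.30 in the pregnant pair. Immediate early genes had a median of -0.20 (camera adjusted p = 0.00923), with -0.50 in the lactating, -0.03 in the pregnant and 0.02 in the virgin pair; over the 3 pairs Fos stood at -0.65 ± 0.16, Ier3 at -0.92 ± 0.26 and Klf6 at -0.78 ± 0.23, while the heat shock gene Hspa1b stood at 0.97 ± 0.27 (SE). Macrophage and dendritic cell genes had a median of -0.11, milk protein genes of -0.10 (camera adjusted p = 0.0422 for each) and B and plasma cell genes of 0.18 (camera adjusted p = 0.0473). The virgin pair was the pair whose arrays differed most in 3' to 5' ratios, 2.74 in the control and 2.04 in the mutant for actin and 3.50 and 1.52 for Gapdh. Without the virgin pair the mitosis median was -0.20, called in the other direction (camera adjusted p = 0.00309), and the muscle median 0.10; without the pregnant pair the milk protein median was 0.11 and the B and plasma cell median -0.02. Not called were homologous recombination genes and Brca1 partners, with a median of 0.13 (camera adjusted p = 0.198), and p53 targets, at -0.01 (camera adjusted p = 0.215). In the pregnant, virgin and lactating pairs the first list had medians of 0.14, 0.29 and -0.01, with the virgin pair at percentile 99.45 of random lists. The p53 targets had medians of -0.24, 0.10 and -0.03, with the pregnant pair at percentile 0.04.

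**Figure D2:**
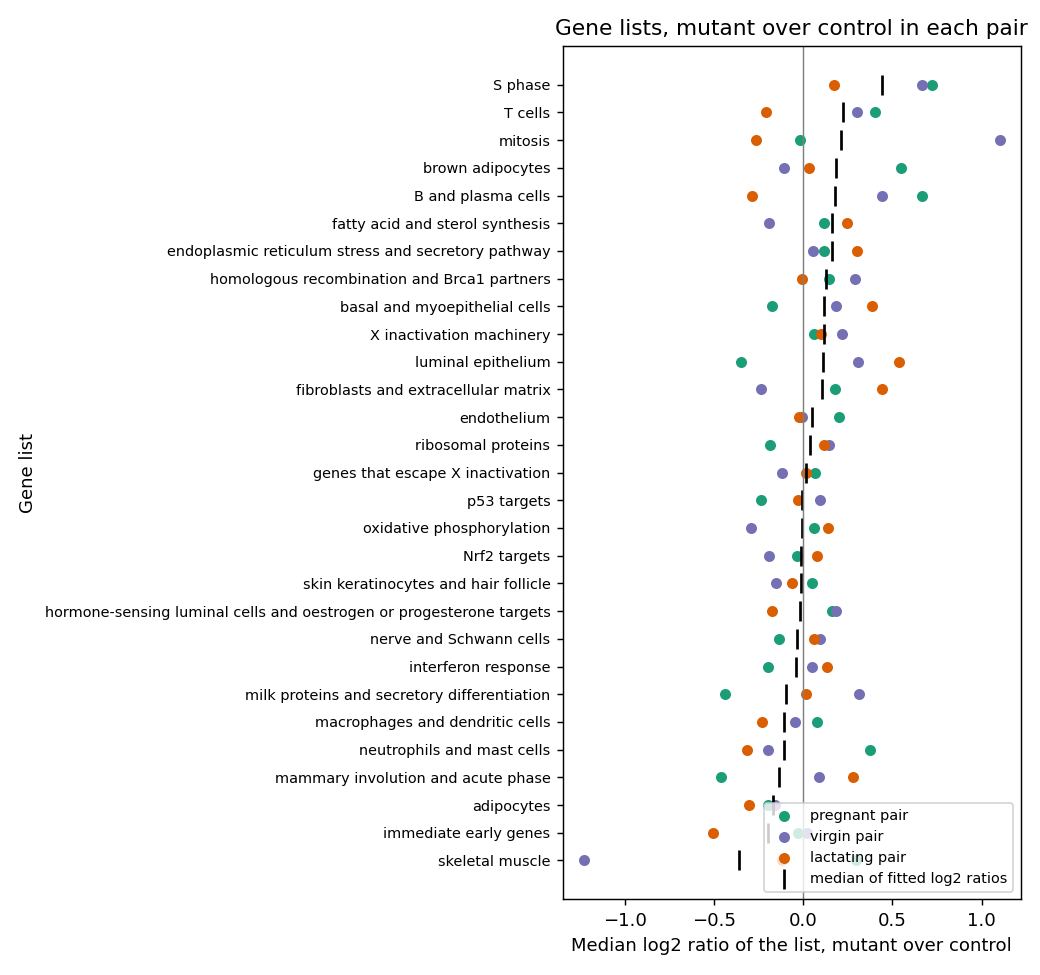
Median log2 ratio of mutant to control (horizontal axis) for each of 29 gene lists (vertical axis), with 1 coloured point per pair and a black bar for the median of the fitted ratios. S phase points lie at 0.72, 0.67 and 0.17, while skeletal muscle points run from -1.23 to 0.30 and mitosis points from -0.26 to 1.10.

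The largest ratios within each pair are given as values, without replicates to test them. Where a signal lay near that of Y-linked probe sets (median 33.6), the ratio depends on the pseudocount and is a lower bound. In the pregnant pair 119 genes were at least 2-fold higher and 102 at least 2-fold lower in the mutant. The acute phase genes Saa1, Saa2 and Saa3 had log2 ratios of -5.41, -4.52 and -2.61, and the milk iron-binding protein Ltf -2.36, while Elovl6, a fatty acid elongase, stood at 2.05. Saa1 had the opposite ratio, 2.34, in the lactating pair. In the virgin pair 165 genes were at least 2-fold higher and 136 lower. The melanosome protein Pmel stood at 2.66, the growth factor Igf2 at 2.22 (a bound, with a control signal of 26.3) and the amino acid transporter Slc7a5 at 1.99, and the myosin heavy chains Myh1, Myh4 and Myh2 at -2.14, -1.86 and -1.79. In the lactating pair 406 genes were at least 2-fold higher and 315 lower. BC018473 on chromosome 11 had a ratio of at least 8.95, with a signal of 30.6 in the lactating control and 4994 to 40978 in the other 5 arrays. St6galnac1, on the same chromosome, stood at 5.11, and Notch4 and D17H6S56E-5, both on chromosome 17, at 5.04 and 4.11. These 4 genes were also at least 2-fold higher in the virgin mutant, at 1.27, 1.04, 1.16 and 1.75. The water channel Aqp5 stood at 3.68 or more (control signal 33.5), and the lowest ratios included Ccn2 at -3.24, the cytokine signalling inhibitor Socs3 at -3.13 and the kinase Sgk1 at -2.98.

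Pregnant glands differed from virgin glands in 1690 genes, 741 higher and 949 lower (limma, 2 arrays per stage). The split depends on scaling: 43.9% of the called genes were higher at the deposited scaling and 26.4% after median centring, which moved the median log2 ratio of all tested genes from -0.06 to -0.24. Milk genes rose: 22 of 29 passed upwards and 1 downwards, with a median of 1.75 (camera adjusted p = 1.137e-18, adjusted p = 0.466 with an estimated correlation). They included the whey acidic protein gene Wap at 5.87 ± 0.36 (SE; limma adjusted p = 0.000552), the milk lipase gene Cel at 4.47 ± 0.19 (0.000121), Lalba, which encodes alpha-lactalbumin, at 4.49 ± 0.32 or more, given its dim virgin signals (0.000922), and the milk fat globule gene Btn1a1 at 3.25 ± 0.20 (0.000552). Lao1, an L-amino acid oxidase, had the largest log2 ratio at 6.69 ± 0.21 (2.765e-05), and the 10 largest also held the fatty acid carrier gene Fabp3 at 5.72 ± 0.40 and the medium-chain thioesterase Olah at 5.04 ± 0.40. Skeletal muscle genes were higher as well, with 27 of 28 called and a median of 2.75 (camera adjusted p = 4.979e-25, 0.466 with an estimated correlation), led by Myh1 at 6.33 ± 0.48 and the myoglobin gene Mb at 4.50 ± 0.28. This list also differed between the glands of 1 stage, with a median of -1.23 for mutant to control in the virgin pair. The agouti pigment gene a read 15640 and 4868 in the pregnant arrays and 78.3 to 185 in the other 4.

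Lymphocyte genes fell from virgin to pregnant glands, and other immune and stromal lists were called lower as groups. T cell genes had a median of -1.71 with 12 of 16 called (camera adjusted p = 4.365e-08), and B and plasma cell genes -1.63 with 14 of 20 called (camera adjusted p = 1.834e-08), with adjusted p = 0.466 and 0.512 with an estimated correlation. The interleukin 7 receptor gene Il7r fell by 2.93 ± 0.23 and Cd3d by 2.95 ± 0.29 (SE). Macrophage, endothelial, fibroblast and adipocyte lists had medians of -0.69, -0.70, -0.71 and -0.66, with 10 of 27, 10 of 22, 8 of 29 and 8 of 24 genes called lower and 1 macrophage gene called higher (camera adjusted p = 0.000159, 3.498e-05, 6.561e-07 and 0.000928; estimated correlation, adjusted p = 0.466, 0.466, 0.540 and 0.466). Foxa1, a transcription factor of hormone-sensing luminal cells, fell by 3.26 ± 0.26 (SE; limma adjusted p = 0.0013). The X inactivation machinery had a median of -0.375, with 19 of 24 genes lower and 2 called (camera adjusted p = 0.0452, 0.466 with an estimated correlation), and 0.0596 with the mean of probe sets. In all 16 lists were called, 0 with an estimated correlation and 1 with fry. The pregnant pair is also the pair with the conditional allele, both virgin mice had 1 normal copy of p53, and ages were 5 against 6 months. Ratios of 3' to 5' signal differed along with stage, at 2.04 and 2.74 for actin in the virgin arrays against 1.43 and 1.37 in the pregnant arrays. For Gapdh they were 1.52 and 3.50 against 0.80 and 0.73. Without the lactating arrays 2759 genes passed, and with a single array left out 304 to 2764 did, the fewest without the virgin control.

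Lactating glands differed from pregnant glands in 3641 genes, 1711 higher and 1930 lower, or 47.0% higher, against 16.6% after median centring, which moved the median log2 ratio of all tested genes from -0.04 to -0.45. Stage cannot be told apart here from array date, from age (2 against 5 months) or from genotype. Both lactating mice had 1 normal copy of p53, and both pregnant mice carried the conditional allele with Cre. Ratios of 3' to 5' signal differed too, at 1.58 and 1.91 for actin in the lactating arrays against 1.43 and 1.37 in the pregnant arrays. For Gapdh they were 1.20 and 1.09 against 0.80 and 0.73. Milk genes were higher as a group at the deposited scaling, with 28 of 29 at a positive ratio and a median of 0.57 (camera adjusted p = 5.02e-05, 0.851 with an estimated correlation). Of these genes 10 were called upwards, 1 was called downwards and 18 were not called. Lalba was higher by 4.56 ± 0.32 (SE; limma adjusted p = 0.000774) and the phosphate transporter Slc34a2 by 3.28 ± 0.24 (0.000811). S phase genes fell, with 17 of 28 called downwards, 1 called upwards and a median of -1.15 (camera adjusted p = 1.779e-06, 0.851 with an estimated correlation). Among them were the replication helicase subunit Mcm6 at -3.86 ± 0.27 or lower and Uhrf1 at -2.51 ± 0.25 (SE). The Mcm6 value is a bound, since its lactating signals of 38.6 and 29.4 were at the level of Y-linked probe sets. Fibroblast and matrix genes fell, with 25 of 29 called and a median of -1.67 (camera adjusted p = 9.692e-13, 0.851 with an estimated correlation), among them Lum at -3.29 ± 0.18 and Col1a2 at -3.03 ± 0.23. Macrophage, adipocyte, oxidative phosphorylation, mitosis and skeletal muscle lists had medians of -1.06, -1.04, -0.57, -0.66 and -1.23 (camera adjusted p = 0.00016, 0.0156, 0.000285, 0.0224 and 6.198e-06; with an estimated correlation, adjusted p = 0.851, or 0.937 for mitosis). Within the mitosis list Tpx2 and Foxm1 went the other way, at 2.78 ± 0.27 and 2.41 ± 0.25. In all 8 lists were called, 0 with an estimated correlation and 0 with fry. Without the pregnant mutant 1029 genes passed and without the pregnant control 1335.

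Lactating and virgin glands were the farthest apart, with 5982 genes called, 2724 higher and 3258 lower, or 45.5% higher, against 18.4% after median centring, which moved the median of all tested genes from -0.10 to -0.69. Stage goes with array date and age here too, and with 3' to 5' ratios, 2.04 and 2.74 for actin in the virgin arrays against 1.58 and 1.91 in the lactating arrays, and 1.52 and 3.50 against 1.20 and 1.09 for Gapdh. Lalba had a log2 ratio of at least 9.05 ± 0.32 (SE; limma adjusted p = 1.786e-05), a bound set by the pseudocount, since its signals of 27.9 and 61.5 in virgin glands were at the level of Y-linked probe sets, against 43159 and 58796 in lactating glands. Lao1 stood at 7.34 ± 0.21 (1.373e-05), the casein gene Csn1s2b at 6.99 ± 0.44 (9.88e-05), the surfactant protein gene Sftpd at 6.25 ± 0.41 (9.88e-05) and the calcium pump gene Atp2c2 at 5.48 ± 0.20 (1.786e-05). The milk list had a median of 2.46 with 24 of 29 called upwards and 2 downwards (camera adjusted p = 8.653e-12, 0.674 with an estimated correlation). Fibroblast and matrix genes fell with a median of -2.41 and 27 of 29 called (camera adjusted p = 8.653e-12, 0.674 with an estimated correlation), among them Lum at -4.74 ± 0.18 and the fibroblast receptor Pdgfra at -4.73 ± 0.34. T cell, B and plasma cell, macrophage, endothelial, adipocyte and S phase lists had medians of -1.94, -1.89, -1.98, -1.30, -1.01 and -1.26 (camera adjusted p = 0.000504 for each but macrophages, 1.43e-05; all 0.674 with an estimated correlation). Skeletal muscle genes had a median of 1.62 (camera adjusted p = 5.72e-07, 0.674 with an estimated correlation). Luminal epithelium genes had a median of 0.41 (camera adjusted p = 0.0399, 0.762 with an estimated correlation) that turned to -0.18 after median centring. The list was still called against the other genes after centring (camera adjusted p = 0.014). In all 10 lists were called, 0 with an estimated correlation and 10 with fry, which were not the same lists: skeletal muscle, B and plasma cell, luminal and S phase lists were not called by fry (adjusted p = 0.154, 0.0652, 0.257 and 0.0652), and fry called the X inactivation machinery, neutrophil and mast cell, nerve and skin lists, which camera did not. Without the virgin control 3408 genes passed.

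**Figure D3:**
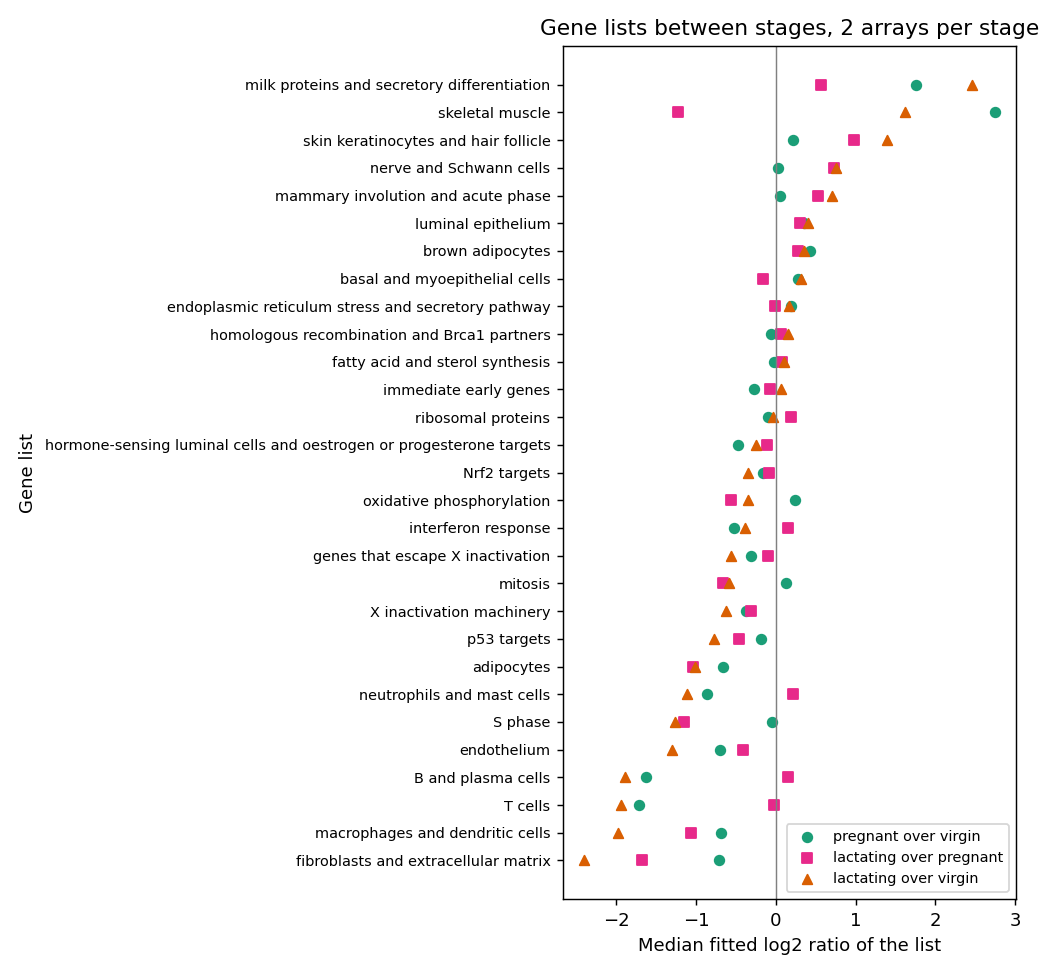
Median fitted log2 ratio (horizontal axis) of each of 29 gene lists (vertical axis) between stages, from 2 arrays per stage, with 1 marker per comparison. Milk genes are higher at each later stage (1.75, 0.57 and 2.46), and fibroblast and matrix genes lower (-0.71, -1.67 and -2.41); medians are at the deposited scaling.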

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

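The tests of lymphoid cells given here were chosen after the results were seen; the other tests were set before their values were computed, but the patterns themselves were found in these data. In 8 gene lists the mutant glands of different pairs stood on opposite sides of their controls, far out among random lists on both sides and at least 0.5 apart; with 1 pair per stage the difference was not tested. The gap between the highest and the lowest pair's median log2 ratio was 1.365 for mitosis, 0.748 for milk proteins, 0.882 for luminal epithelium, 0.563 for basal and myoepithelial cells, 0.953 for B and plasma cells, 1.526 for skeletal muscle, 0.681 for fibroblasts and extracellular matrix, and 0.739 for involution and acute phase genes. Lists for fatty acid and sterol synthesis, oxidative phosphorylation and ribosomal proteins also stood far out on both sides, with smaller gaps, which were not tested. For skeletal muscle in the virgin pair, a second list of 23 muscle genes had a median of -0.318 against -1.229 for the first, between the bounds set beforehand, and the first came no closer to 0 than -1.166 under quantile normalization or median centring.

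The S phase genes, higher in the mutant with a median of 0.44, had the lowest p of the lists. Array scaling is argued against: under quantile normalization or median centring the mean of the pair medians came no closer to 0 than 0.482. More lymphoid cells in the mutant gland, as dividing cells of another type, may account for part of it in the pregnant and virgin pairs, where the lowest of the T and B cell medians was 0.299 and above 0. The mitosis median, however, was 1.10 in the virgin pair and -0.02 in the pregnant pair. That list therefore gives no sign of more dividing cells in the pregnant pair. In the lactating pair T and B cell genes were lower, but the S phase median was only at percentile 93.92 of random lists, so nothing there was large enough to decide. Of the 4 ways to part all 3 pairs, the real one gave a median of 0.44 and the highest other 0.444, with 2 as large counting the real one, and 4 splits are too few for a share under 0.05; a biological effect of Brca1 loss stays open too, untested.

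For the counts of calls the 4 splits are likewise too few. They gave 0 genes in the real split and 0 at most in the others (4 of 4 as large, counting the real one), and 9 lists against 13 (3 of 4 as large). The other 6 of the 10 splits part 1 pair only and give the same fit for each pair in duplicate. Such a fit sets the ratios of 1 pair against the spread of the other 2 pairs, so its calls rest on 1 pair. The SD of the ratios across genes was 0.545 in the lactating, 0.379 in the pregnant and 0.407 in the virgin pair.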

How the results depend on the processing

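The alternative without the lactating arrays was chosen after seeing the data; the others were planned. The X shift stayed between -0.0324 and -0.00333 with no call under any alternative. Without the replicate block, 0 genes and 6 lists were called between mutant and control, and the milk protein, B and plasma cell and macrophage lists lost their call. The mutant count stayed at 0 but for the fit without the lactating pair (range 0 to 2). The 9 mutant lists became 5 with the mean of probe sets and 0 with an estimated correlation, which also gave 0 lists for each pair of stages. Leaving out 1 array gave 304 to 2764 genes for pregnant against virgin, 1029 to 3511 for lactating against pregnant and 3408 to 5636 for lactating against virgin; without the lactating arrays the first was 2759. A filter at the 75th percentile, which tests fewer genes, gave 2139 and 3620 for the last 2, and no filter gave 16 lists for lactating against virgin. Genes at least 2-fold apart in the pregnant, virgin and lactating pairs (221, 301 and 721) numbered 91, 122 and 387 with a pseudocount at the median, 674, 743 and 1662 with no filter and 82, 122 and 292 with the 75th percentile filter; the mean of probe sets gave 181 in the virgin pair. Reversed in sign were Xist (-0.025 with median centring, -0.189 with the mean of probe sets), Otud5 (-0.017 with the mean of probe sets) and Rtel1 in the pregnant pair (0.355 with a pseudocount at the 10th percentile). Leaving out a pair gave medians of -0.243 to 0.112 for milk proteins, -0.0183 to 0.472 for B and plasma cells, -0.20 to 0.457 for mitosis and -0.756 to 0.0986 for skeletal muscle, and -0.106 to 0.162 for Xist. The X inactivation machinery, at -0.375 for pregnant against virgin, was at 0.0596 with the mean of probe sets. Luminal epithelium ranged from -0.0445 to 0.720 for pregnant against virgin with 1 array left out, and was -0.181 for lactating against virgin after median centring. Median centring moved the median of all tested genes from -0.10 to -0.69 for lactating against virgin. There the luminal list was still called (camera adjusted p = 0.014). For mutant against control centring moved the median of all tested genes from 0.03 to -0.01. The mean of probe sets for Xist takes in its other 2 probe sets, at -0.15 and -0.43. That of Otud5 takes in 2 of its 4 probe sets with the opposite sign. For Rtel1 the probe set used in the main setting read 1893.8 in the pregnant control and 59.8 in the mutant. Its ratio is negative at any pseudocount, so the reversal came from another of the 4 Rtel1 probe sets being taken. The cause of the remaining reversals was not tested. In 57 cases a list median kept its direction but lost the call. Dim signals set the depth limit, since Y-linked probe sets reached 483.5.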

Other observations

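The tests of neighbouring genes here were chosen after the results were seen; the clock gene lists were written before their medians were computed, after Dbp and Nr1d2 had been seen among the lowest ratios. Gene groups not described above are given first as values. Hormone-sensing luminal genes had a median of -0.47 from virgin to pregnant (camera adjusted p = 0.0539), and Cited1 fell by 2.63 ± 0.35 and Cxcl12 by 1.71 ± 0.19 (SE; limma adjusted p = 0.00523 and 0.00331). Interferon response genes had a median of -0.52 there (camera adjusted p = 0.000839, 0.540 with an estimated correlation), with Cxcl9 at -2.00 ± 0.23. In the pregnant pair BC018473, St6galnac1, Notch4 and D17H6S56E-5 were at -0.28, -1.14, -0.08 and -0.12; the difference from the other pairs was not tested.

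Clock genes of the day phase, a list of 10 that includes Dbp and Nr1d2, had medians of -0.393, 0.111 and -1.243 in the pregnant, virgin and lactating pairs, a mean of -0.508 that is smaller than its SD of 0.684, and 0 members passed with limma (4 had an unadjusted p under 0.05). Under quantile normalization or median centring the mean came no closer to 0 than -0.547, also within that SD, and since the genes that prompted the list are part of it, scaling stays open. A different time of day at collection may be the source: 5 clock genes of the opposite phase had a mean median of 0.313, with medians above 0 in all 3 pairs (0.511, 0.216 and 0.211). The virgin pair's day-phase median, above 0, keeps this open. No biological explanation was tested, and an effect of Brca1 on the clock stays open.

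Genes with large ratios sometimes lay side by side, such as BC018473 and St6galnac1, which raised the hypothesis of stretches of chromosome from different parental strains in this mixed background. In the virgin pair 15 adjacent pairs of genes with unlike names were both at least 2-fold apart, against a median of 7 in 10000 random draws (96 draws gave as many). In the lactating pair there were 46 against 43 (3441 draws gave as many), and in the pregnant pair 6 against 4. The counts thus disagree between the pairs of mice. BC018473 with St6galnac1, and D17H6S56E-5 with Vars, were adjacent at that size in both germline pairs, higher in both mutants. Naaladl2 with Ect2, and Calml3 with Net1, were too, but higher in the virgin and lower in the lactating mutant. In the pregnant pair Vars stood at 0.49. The hypothesis is neither borne out nor excluded. A stretch carried along with the Brca1 allele was not borne out either. The window of Brca1 and the 100 tested genes on each side was set against autosomal windows of that size. It held 10 genes at least 2-fold apart in the lactating pair, against a median of 12 (percentile 20.67). In the virgin pair it held 6 against a median of 5 (percentile 66.86), and Brca1 itself, at 1.51, is counted among those 6. Brca1 lies on chromosome 11, as do BC018473 and St6galnac1, and whether the window reaches those genes was not examined. A linked stretch therefore stays open. Signals cannot tell a change in expression from a strain variant under a probe.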
